A study of Mus musculus with 16 samples.

How the data were processed

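RNA from 16 cultures of adult mouse neural stem cells was measured, 1 array per sample. Per the labels, total RNA was extracted with TRIzol and labelled with biotin by the ENZO in vitro transcription kit. The deposited table holds 1 intensity (linear signal) per probe set and array; the submitters' processing notes name MAS5, with version and scaling target not given in the sources used here. Replicates were not pooled in the deposited table. Its signals are positive and linear. Median signal per array lay between 92.2 and 132.6 and the brightest array was 1.44 times the dimmest, under the limit of 1.5 set beforehand, so the main values were not rescaled; residual differences in brightness between arrays then count as spread and shift all genes of an array together. No scanner files or presence calls were used here. Arrays have no read depth, and their number limits the precision.

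Samples were grouped by their titles into genotype (CreER or no Cre), treatment (4-hydroxytamoxifen or vehicle) and time (36 h or 60 h). Of 22690 probe sets, 64 controls were left out. Of the other 22626, 20380 were listed with 1 gene symbol, 691 with several and 1555 with none; a probe set with none is unnamed here. Symbols came from the platform annotation and were looked up by Entrez ID in a RefSeq gene table of assembly GRCm38.p6, used for names only: 20364 of 20393 matched, with controls counted, and 0 symbols changed. For each of 12393 genes the probe set with the highest mean log2 signal was used, and for genes named for their largest changes, other probe sets past the filter are given where their change was much smaller or opposite. Genes were tested if their mean log2(signal + 16) reached the 40th percentile of all probe sets, 6.07 on that scale or a signal of 51.1, which left 7619. Fold changes are on the log2(signal + 16) scale, which understates the change of dim genes; signal means are linear.

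All 16 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3) of 8 group means with 8 residual degrees of freedom, with contrasts, empirical Bayes moderation with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment within each contrast at 0.05. Contrasts were 4OHT against vehicle in CreER cultures over both times, at 36 h and at 60 h; the same in cultures without Cre; the difference of these responses; the difference of the CreER response between times; CreER against no Cre under vehicle; and 60 h against 36 h over the 4 conditions. The prior degrees of freedom were infinite in this fit, against 632 with no trend, 11.1 after median scaling and 6.84 after quantile normalization. Each gene's variance was thus set by the shared trend alone, so adjusted p-values of single genes assume that genes of like brightness vary alike. The smallest limma adjusted p for 4OHT in CreER cultures over both times was 1.27e-30 as deposited and 1.35e-10 after quantile normalization. Tested on simulated data for the CreER comparison over both times (7619 genes), the fit recovered 44 of 67 genes changed 1.5-fold (65.7%), 66 of 67 changed 2-fold (98.5%) and 66 of 66 changed 3-fold, with 1 false call. The simulated arrays differed in brightness only within groups, and noise was drawn for each gene independently. False calls from brightness differences between groups were therefore not measured.

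Before the data were examined, 22 gene lists were fixed: DNA replication and G1/S, mitosis and G2/M, p53 targets and CDK inhibitors, neural stem and progenitor cell, astrocyte, neuron, oligodendrocyte lineage, Wnt, Notch, BMP and TGF-beta, sterol synthesis, hypoxia and glycolysis, interferon, integrated and ER stress, immediate early, estrogen receptor response, reported TLX-regulated genes, microglia, endothelial and mural, fibroblast and meningeal, ependymal, and sex-linked. Lists share members, such as Mki67 in the mitosis and stem cell lists and Cdkn1a in the p53 and TLX lists. Members past the threshold were counted over all genes and adjusted over the list alone, and lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists. With the correlation estimated from the data as deposited, no list kept its call in any comparison. After quantile normalization and with an estimated correlation, the calls of the replication (adjusted p = 5.19e-04), mitosis (8.73e-05), p53 (5.19e-04) and immediate early lists (0.0365) held for CreER cultures over both times.

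Named genes were chosen by a rule fixed before the files were seen: among genes past the threshold whose 2 treated and 2 control arrays did not overlap at the time compared (in pooled comparisons, whose mean difference had the same sign at each time), the 12 with the largest rise and the 12 with the largest fall. Where fewer passed, those were named with up to 5 more per direction, said not to pass. From each fixed list the 2 to 4 measured members with the smallest p could be named. For the comparisons of time and of the CreER response between times the sign condition was not applied, so a gene named there need not have moved alike in each condition.

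Alternatives were pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, quantile normalization, scaling to a common median, a replicate block, no trend, a robust trend, all probe sets, the compared arrays alone, and leaving out each array in turn. An actin ratio covariate, the contrasts without the 36 h cultures lacking Cre, and the estimated correlation after quantile normalization were added after the data were seen. Simulation, counting of other splits and list tests ran in R, and plots in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Nr2e1 is not analysed here.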

Results

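Cultured adult mouse neural stem cells were profiled on Affymetrix arrays to ask which genes depend on Tlx, the orphan nuclear receptor encoded by Nr2e1 that keeps these cells in a proliferating, undifferentiated state. All cultures carried the genotype written Tlx(f/Z) in the labels, where f commonly stands for an allele that a recombinase can delete. They either also carried CreER, a Cre recombinase fused to an estrogen receptor domain and activated by 4-hydroxytamoxifen (4OHT), or carried no Cre. Each kind was treated with 4OHT or vehicle and collected at 36 h or 60 h, which gave 8 groups of 2 arrays, 16 arrays in all. The design text calls the 2 arrays of a group biological replicates without saying whether they came from separate animals, so p-values measure the spread between these samples only. Nr2e1 itself was not analysed here, because 0 probe sets were listed under its symbol in the annotation used, and the labels were therefore not checked by the targeted gene. The Esr1 probe set, which may or may not lie in the part of the receptor carried by CreER, gave a signal of 382 ± 55.1 (SD, n = 8) in CreER arrays and 21.3 ± 6.92 (SD, n = 8) in arrays without Cre, with no overlap between individual arrays. Replicates correlated across probe sets at r = 0.992 to 0.994, against a median of 0.945 between arrays of different genotype. Median signal per array ran from 92.2 to 132.6, and the number of arrays limits the precision. The ratio of 5' to 3' actin control signal, a measure of RNA integrity and labelling, was 0.614 ± 0.0534 (SD, n = 4) in cultures without Cre at 36 h and 0.825 ± 0.0548 (SD, n = 4) at 60 h. In CreER cultures it was 0.776 ± 0.0454 (SD, n = 4) at 36 h and 0.826 ± 0.0729 (SD, n = 4) at 60 h. The same ratio of the Gapdh controls was 0.975 ± 0.125 at 36 h and 1.23 ± 0.0262 at 60 h without Cre (SD, n = 4 each). With CreER the Gapdh ratio was 1.22 ± 0.0405 at 36 h and 1.22 ± 0.0374 at 60 h (SD, n = 4 each).

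The central comparison set 4OHT against vehicle in CreER cultures over both times, the contrast in which the recombinase can act on the f allele. Of the fixed lists, 30 of 31 replication genes and 30 of 33 mitosis genes fell, and 12 of 22 p53 targets and CDK inhibitors rose. As sets these calls were lost with an estimated correlation as deposited (adjusted p = 0.18 each). With an estimated correlation after quantile normalization they held (camera adjusted p = 5.19e-04, 8.73e-05 and 5.19e-04 in that order). The strongest rises were those of Cryab, a small heat-shock protein, from a signal of 56.4 ± 25.4 to 223 ± 111 (SD, n = 4 each), and of Klf2, a transcription factor linked to quiescence, from 156 ± 76.8 to 469.8 ± 155 (SD, n = 4 each). Dcxr, Cox8b, Ptp4a3, Pygm (muscle glycogen phosphorylase) and Gsn (gelsolin) rose by 1.27 to 1.54 on the log2 scale. Chek1, the checkpoint kinase of stalled replication forks, fell by 1.15 on the log2 scale, from 222 ± 48.2 to 94.7 ± 37.7 (SD, n = 4 each). E2f8 (−1.03), Timeless (−0.97), Brca1 (−0.96) and Blm (−0.96) fell with it; Timeless, Brca1 and Blm act in replication or DNA repair. Car3, a carbonic anhydrase, fell by 0.94 on the log2 scale. The second probe set of Chek1 gave −0.62. For each gene named in these sentences, by the probe set used, both 4OHT arrays lay on the same side of both vehicle arrays at each time, and adjusted p lay between 1.27e-30 for Cryab and 4.66e-09 for Car3.

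Of the 31 measured genes for DNA replication and G1/S entry, 30 fell, 0 rose and 1 did not pass the threshold, and 31 fell when adjusted over the list alone. Its median change was −0.63 (adjusted p = 4.76e-31; adjusted p = 0.18 with an estimated correlation). Pola1 (−0.91), Mcm10 (−0.87), Tk1 (−0.77) and Mcm2 (−0.73), a polymerase, helicase components and thymidine kinase, stood out among its members. Of 33 measured mitosis and G2/M genes, 30 fell and 3 did not pass, with 32 lower when adjusted over the list alone. The median was −0.57 (adjusted p = 1.35e-26; adjusted p = 0.18 with an estimated correlation). Mki67, the proliferation antigen, went from 1969 ± 544 to 1124 ± 322 (SD, n = 4 each), and Ttk, Bub1 and Top2a fell by 0.73 to 0.90 on the log2 scale. Among 22 measured p53 targets and CDK inhibitors, 12 rose, 1 fell and 9 did not pass (14 higher and 1 lower when adjusted over the list alone), with a median of 0.47 (adjusted p = 2.10e-19; adjusted p = 0.18 with an estimated correlation). Cdkn1a, the CDK inhibitor p21, rose from 1540 ± 264 to 3015 ± 398 (SD, n = 4 each), and Bbc3 (1.12), Trp53inp1 (1.06) and Phlda3 (0.95) rose with it. Of 20 measured immediate early genes 7 rose and 13 did not pass, with 8 higher and 1 lower when adjusted over the list alone. The median was 0.21 (adjusted p = 8.42e-09; adjusted p = 0.35 with an estimated correlation). Klf2, Dusp1 (0.91), Klf4 (0.79) and Btg2 (0.63) were the leading members.

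Of 10 measured genes reported elsewhere as regulated by TLX, 3 rose, 0 fell and 7 did not pass (3 higher and 1 lower when adjusted over the list alone): Cdkn1a (0.97), the astrocyte calcium-binding protein S100b (1.05) and the deacetylase Hdac5 (0.37). The camera test called that list higher (adjusted p = 0.0171; adjusted p = 0.76 with an estimated correlation) while its median was −0.12. The signs of median and test thus differed. Reports on these cultures may be among the sources of the list, which is then not independent evidence. In the interferon list 2 of 6 measured members rose, also when adjusted over the list alone, Tap1 (0.65) and Ifitm3 (0.39), with a median of 0.14 (adjusted p = 0.0266; adjusted p = 0.65 with an estimated correlation). Of 9 measured estrogen receptor response genes 2 rose, also when adjusted over the list alone, Ctsd (0.44) and Cited2 (0.40), with a median of 0.16 (adjusted p = 0.0324; adjusted p = 0.76 with an estimated correlation).

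The other lists did not pass as sets, with adjusted p between 0.0871 and 0.86. Of 26 measured integrated and ER stress genes 5 rose and 2 fell (6 and 3 when adjusted over the list alone), led by Trib3 (0.80) and Ddit3 (0.75). Of 19 hypoxia and glycolysis genes 1 rose, Ddit4 (0.56), and 4 fell, with Egln3 (−0.71) and Pdk1 (−0.59) lowest (1 and 5 when adjusted over the list alone). Of 23 neural stem and progenitor cell genes 4 fell, also when adjusted over the list alone, namely Mki67, Pax6 (−0.40), Lfng (−0.38) and Fabp7 (−0.27). The astrocyte list had 4 higher and 4 lower of 17, among them S100b, Clu (0.45) and Slc4a4 (−0.60), with 4 and 5 when adjusted over the list alone. The neuron list had 2 higher, Mapt (0.84) and Syt1 (0.49), and 2 lower, Map2 (−0.38) and Sox11 (−0.41), of 12, also when adjusted over the list alone. Lef1 (0.49) was the 1 of 18 Wnt genes past the threshold. Nrarp (−0.46) and Lfng were 2 of 13 Notch genes, and Skil (−0.44) and Id3 (−0.35) were 2 of 9 BMP and TGF-beta genes past it; these numbers were the same when adjusted over the list alone. Of 7 oligodendrocyte lineage and 19 sterol synthesis genes 0 passed, with limma at 0 also when adjusted over the list alone. Markers of other cell types were mostly below the filter: 1 microglial, 2 endothelial and mural, 3 fibroblast and meningeal, 3 sex-linked and 0 ependymal genes were measured, and 0 of these passed.

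Over all 7619 genes tested with limma, 305 were higher and 637 lower after 4OHT in CreER cultures, 942 in total at an adjusted p under 0.05. The split turned to 1492 higher and 1459 lower after quantile normalization and to 1056 and 1457 after scaling each array to a common median. The balance of the directions hung on single arrays: it was 438 higher and 354 lower without CreER vehicle 60 h replicate 1, 398 and 335 without CreER 4OHT 60 h replicate 1, and 183 and 1043 without CreER 4OHT 60 h replicate 2. The total fell to 580 when the spread came from CreER arrays alone and to 547 with no filter. It was 622 without CreER vehicle 36 h replicate 2, 520 without CreER 4OHT 36 h replicate 1 and 584 without CreER 4OHT 36 h replicate 2.

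**Figure D1:**
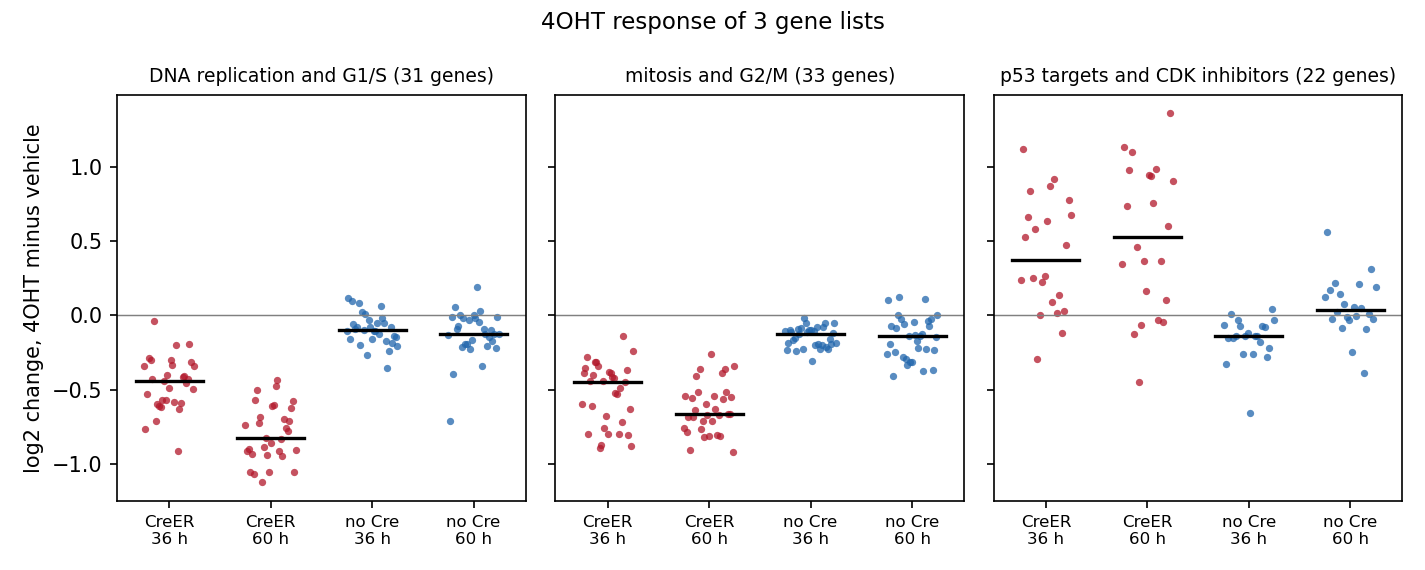
Log2 change (4OHT minus vehicle, y axis) of each measured member of the replication, mitosis and p53 lists in CreER and no-Cre cultures at 36 h and 60 h, one point per gene with a bar at the median. In CreER cultures the replication medians are −0.44 at 36 h and −0.82 at 60 h; over both times without Cre the median is −0.12.

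**Figure D2:**
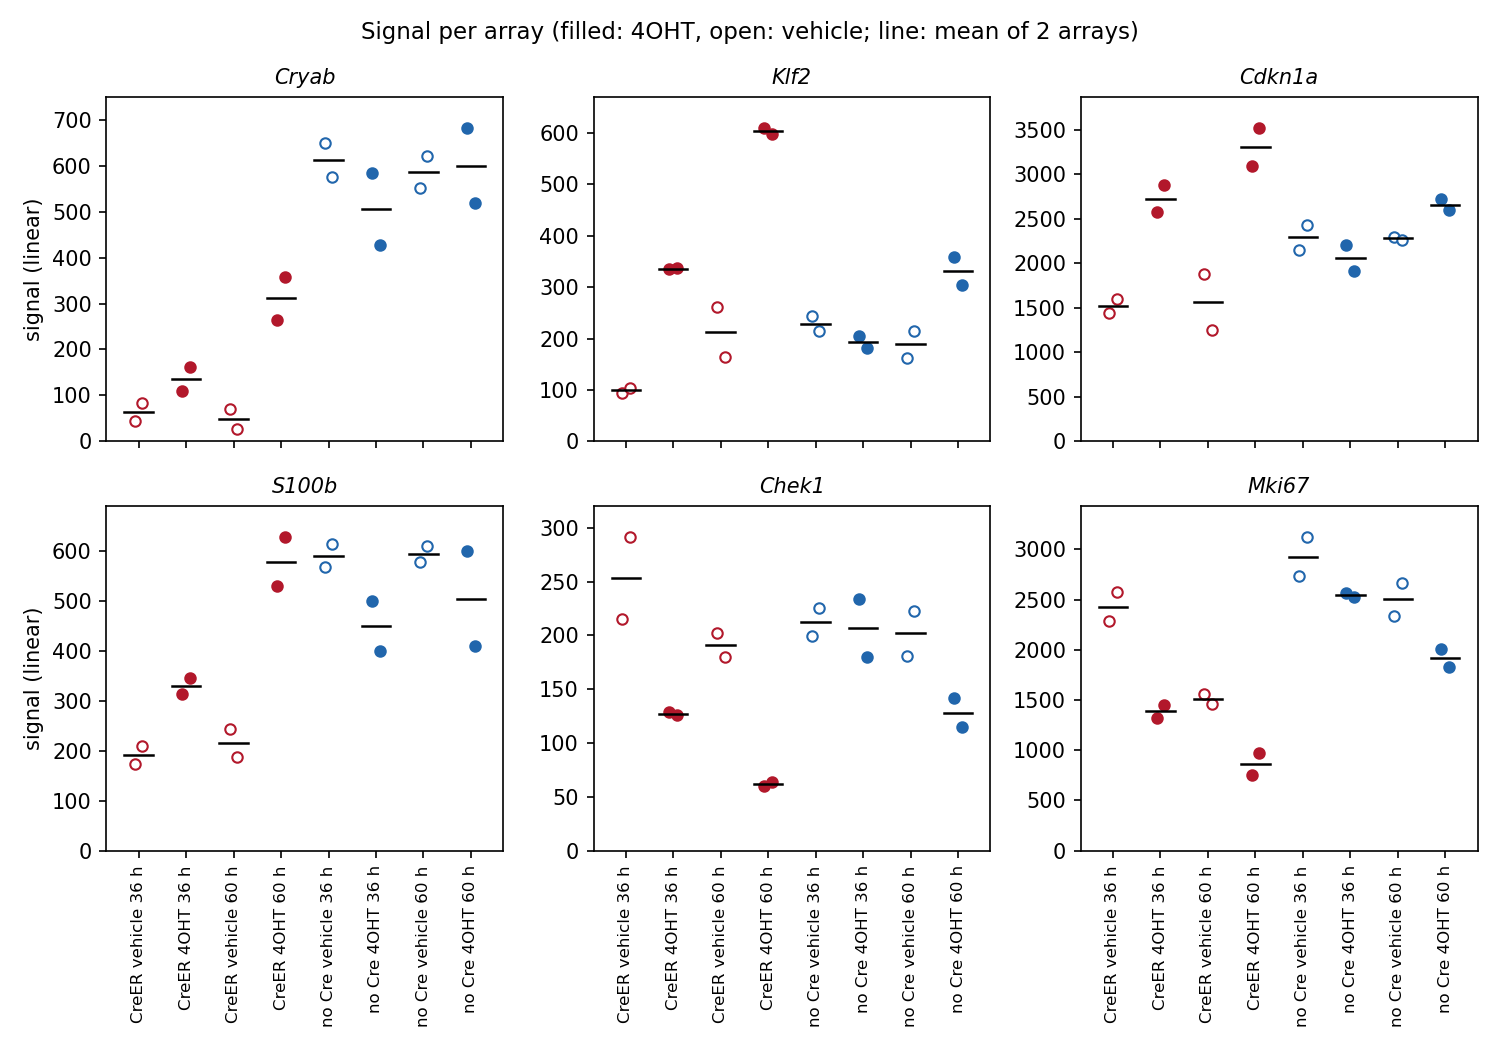
Signal per array on a linear axis for Cryab, Klf2, Cdkn1a, S100b, Chek1 and Mki67 in the 8 groups, with filled points for 4OHT, open points for vehicle and a line at the mean of 2 arrays. Cryab in CreER cultures at 60 h has means of 48.9 with vehicle and 312 with 4OHT, and all arrays without Cre lie above both.

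At 36 h, the early time point, part of the replication and mitosis genes were already lower and part of the p53 targets higher in CreER cultures treated with 4OHT. Klf2 rose from 99.3 ± 5.76 to 336 ± 1.69 (SD, n = 2 each), and Dcxr (1.31), the stress kinase-like gene Trib3 (1.28), Anxa1 (1.16), the tau gene Mapt (1.15) and Bbc3 (1.12) rose with it. Myef2 (−0.96), Pola1 (−0.91), Chek1 (−0.90), Cenpe (−0.89), Ttk (−0.88) and Cenpf (−0.87) fell. Among the largest falls were also genes outside the fixed cell-cycle lists, namely Fancm (−0.97), Adamts5 (−0.96), Fam126b (−0.95), Uroc1 (−0.93), Plagl1 (−0.86) and Tead1 (−0.84). Other probe sets gave 0.31 for Mapt, 0.74 for Trib3, −0.43 for Myef2 and −0.26 for Adamts5. In a fit of all probe sets with no filter, Uroc1 had −0.93 with a standard error of 0.64. Both 4OHT arrays lay beyond both vehicle arrays for each of these genes by the probe set used, which the naming rule required. Their adjusted p ran from 7.21e-13 for Klf2 to 0.0419 for Tead1. Of the replication genes 7 of 31 fell (21 when adjusted over the list alone; median −0.44, adjusted p = 1.75e-17) and of the mitosis genes 13 of 33 fell (21 when adjusted over the list alone; median −0.45, adjusted p = 1.23e-23). Of 22 p53 targets and CDK inhibitors 7 rose (11 when adjusted over the list alone; median 0.37, adjusted p = 5.45e-13), among them Cdkn1a (0.84), Phlda3 (0.92) and Gadd45g (0.87). With an estimated correlation as deposited each of these lists had an adjusted p = 0.41. After quantile normalization with an estimated correlation, camera gave adjusted p = 0.0011 for replication, 8.6e-05 for mitosis and 0.0011 for p53. Stress response genes rose more often than they fell: 5 of 26 were higher and 1 lower (7 and 1 when adjusted over the list alone; adjusted p = 0.00165; adjusted p = 0.75 with an estimated correlation), with Trib3, Slc7a11 (0.88), Ddit3 (0.77) and Cebpb (0.71) among the risers. Of 20 immediate early genes 4 rose (6 higher and 1 lower when adjusted over the list alone; median 0.25, adjusted p = 2.46e-07; adjusted p = 0.47 with an estimated correlation). Of 6 interferon genes 0 passed, also when adjusted over the list alone, with a median of 0.32 (adjusted p = 0.00831; adjusted p = 0.47 with an estimated correlation). Of 19 hypoxia genes 3 fell, Bnip3 (−0.72), Egln3 (−0.76) and Pdk1 (−0.65), and 1 rose, Ddit4 (0.61), with 4 and 1 when adjusted over the list alone. Their median was −0.13 (adjusted p = 0.0889; adjusted p = 0.75 with an estimated correlation). In total 85 genes were higher and 114 lower, 199 of 7619, against 740 and 894 after quantile normalization and 361 and 1103 after median scaling. With the actin ratio as a covariate the split was 132 higher and 70 lower. Without vehicle replicate 2 it was 65 and 13, and without 4OHT replicate 1 it was 24 and 7, so the balance hung on single arrays. The total was 14 with no filter, 348 with the spread taken from these 4 arrays alone, and 58 or 78 without vehicle replicate 1 or 2 and 31 or 38 without 4OHT replicate 1 or 2.

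At 60 h 533 genes passed the threshold against 199 at 36 h, but that order turned, to 53 against 348, when the spread came from the 4 arrays compared alone. Cryab rose by 2.40 on the log2 scale, from 48.9 ± 29.7 to 312 ± 65.9 (SD, n = 2 each), and Cox8b by 2.24. Dcxr (1.77), Ptp4a3 (1.64), Pygm (1.63), Gsn (1.53), the forkhead factor Foxo3 (1.41) and S100b (1.37) rose too, and Trp53inp1 (1.36), Cdkn1a (1.10), Ccng1 (0.98) and Bbc3 (1.13) led the p53 list. E2f8 fell from 403 ± 52.0 to 141 ± 9.88 (SD, n = 2 each), and Chek1 (−1.41), Lrrc1 (−1.28), Fignl1 (−1.15), Timeless (−1.13), Mcm10 (−1.12) and Brca1 (−1.11) fell with it. Other probe sets gave 0.44 for Foxo3 and −0.69 for Chek1. By the probe set used, for the genes named so far at 60 h both 4OHT arrays lay beyond both vehicle arrays, with adjusted p from 1.40e-31 for Cryab to 1.98e-05 for Bbc3. The naming rule required this of the genes with the largest changes. The median of all genes shifted by −0.11, so list medians are given relative to it. Of the replication genes 28 of 31 fell (31 when adjusted over the list alone), with a relative median of −0.72 (adjusted p = 1.05e-32; adjusted p = 0.30 with an estimated correlation). Tk1 (−1.05), Mcm5 (−1.05) and Chaf1b (−1.07) were among them. Of the mitosis genes 25 of 33 fell (30 when adjusted over the list alone), with a relative median of −0.56 (adjusted p = 1.63e-19; adjusted p = 0.31 with an estimated correlation). Of the p53 targets and CDK inhibitors 11 of 22 rose and 0 fell (12 and 1 when adjusted over the list alone), with a relative median of 0.63 (adjusted p = 2.90e-18; adjusted p = 0.30 with an estimated correlation). After quantile normalization with an estimated correlation, camera gave adjusted p = 4.6e-04 for replication, 1.2e-04 for mitosis and 4.6e-04 for p53. Of 20 immediate early genes 7 rose, also when adjusted over the list alone, including Dusp1 (1.10), Klf4 (0.90) and Fos (0.77) (adjusted p = 3.96e-07; adjusted p = 0.49 with an estimated correlation). Of 10 reported TLX-regulated genes 2 rose, S100b and Cdkn1a, also when adjusted over the list alone; the test pointed up (adjusted p = 0.0239; adjusted p = 0.86 with an estimated correlation) and the relative median was −0.045, so they differed in sign. Altogether 180 genes were higher and 353 lower, 533 of 7619, against 1233 and 1029 after quantile normalization and 1039 and 753 after median scaling. The split was 240 higher and 81 lower without vehicle replicate 1, 237 and 119 without 4OHT replicate 1, 81 and 620 without vehicle replicate 2 and 76 and 566 without 4OHT replicate 2, so single arrays set the balance. The total was 253 with no filter, 970 with the actin ratio as a covariate (109 higher, 861 lower) and 321 without vehicle replicate 1.

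The responses at 36 h and 60 h share no arrays and overlapped: 48 genes were higher at both, where independent lists of 85 and 180 would share 2.01, and 67 were lower at both, where lists of 114 and 353 would share 5.28. Across the 7619 genes the log2 changes at 36 h and 60 h correlated at r = 0.58 (Spearman rho = 0.54); genes are not independent replicates. A test of the difference itself found that the 4OHT response was higher at 60 h than at 36 h for 7 genes and lower for 8. Triap1, a p53-regulated survival gene, had the largest such rise (1.83, adjusted p = 8.97e-08), followed by Arid5a (1.57), Fam126b (1.47), Cryab (1.46), Cox8b (1.40), Uroc1 (1.18) and Cp (1.10). Lrrc1 (−1.55), Gm6211 (−1.39), Acaca (−1.36), Abcb8 (−1.33), Kcnd3 (−1.32), Dlg4 (−1.31), Spry4 (−1.28) and Lysmd2 (−1.15) went the other way, with adjusted p from 0.00241 to 0.0399. No condition on overlap of single arrays was applied to these genes, whose differences rest on 2 arrays in each of 4 groups. Between 36 h and 60 h the actin ratio went from 0.745 to 0.872 with vehicle and from 0.807 to 0.780 with 4OHT. RNA quality was therefore not separated from these differences. Of the replication genes 0 of 31 differed between times, also when adjusted over the list alone, and their median difference was −0.35 (adjusted p = 1.97e-07; adjusted p = 0.96 with an estimated correlation). Of 22 p53 targets and CDK inhibitors 0 passed, also when adjusted over the list alone, with a median of 0.093 (adjusted p = 0.0125; adjusted p = 0.96 with an estimated correlation). Of 26 integrated and ER stress genes 0 passed (7 lower when adjusted over the list alone), with a median of −0.14 (adjusted p = 0.0153; adjusted p = 0.96 with an estimated correlation). The mitosis list gave a median of −0.098 (adjusted p = 0.74). Other probe sets gave −0.25 for Abcb8, 0.61 for Cryab and 0.12 to 0.81 for Cp. In a fit of all probe sets with no filter, Uroc1 had 1.18 with a standard error of 0.91. The split of 7 higher and 8 lower became 111 and 56 after quantile normalization and 145 and 15 after median scaling. The total of 15 was 0 with no filter (326 genes had an unadjusted p under 0.05 in limma with the filter), 7 and 9 without CreER 4OHT 36 h replicates 1 and 2, and 29 and 6 without CreER 4OHT 60 h replicates 1 and 2.

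Cultures without Cre served as the control for the compound itself. Here Igfbp5, a binding protein of insulin-like growth factors, fell from 989 ± 54.1 to 546 ± 56.7 (SD, n = 4 each; log2 change −0.84, adjusted p = 1.09e-06), and the nuclear noncoding RNA Malat1 fell by 0.77 on the log2 scale (adjusted p = 1.09e-06). All 5 probe sets of Malat1 were lower, by −0.60 to −0.96. Acss1 (−0.67) and Msx1 (−0.60) fell and Trib3 rose (0.63), each with an adjusted p = 0.0483. Other probe sets gave 0.32 for Trib3 and −0.50 for Igfbp5. Both 4OHT arrays were below both vehicle arrays at each time for Igfbp5, Malat1 and Acss1; those of Msx1 overlapped at 60 h and those of Trib3 at 36 h. Of 26 integrated and ER stress genes 1 rose, Trib3 (5 when adjusted over the list alone), with a median of 0.11 (adjusted p = 3.74e-16; adjusted p = 0.85 with an estimated correlation), and Eif4ebp1 (0.38), Chac1 (0.38) and Asns (0.32) had values on the same side without passing. By time, at 36 h 0 of 26 passed and the median was −0.10 (adjusted p = 0.99), while at 60 h 6 rose (10 when adjusted over the list alone) with a median of 0.33 (adjusted p = 1.25e-19; adjusted p = 0.58 with an estimated correlation). The difference between these times was not tested. At 60 h the actin ratio was 0.781 ± 0.0104 with vehicle and 0.870 ± 0.0288 with 4OHT (SD, n = 2 each), without overlap. By that control these values were not separated from RNA quality. The Gapdh ratio was 1.24 ± 0.0185 with vehicle and 1.23 ± 0.0414 with 4OHT (SD, n = 2 each), with overlap. Among 31 replication, 33 mitosis, 19 sterol synthesis, 19 hypoxia and 17 astrocyte genes 0 passed in limma, also when adjusted over each list alone. As sets these had medians of −0.12 (adjusted p = 0.0247), −0.15 (adjusted p = 2.98e-05), 0.068 (adjusted p = 5.02e-04), −0.091 (adjusted p = 0.009) and −0.15 (adjusted p = 0.041). Each had an adjusted p = 0.94 with an estimated correlation as deposited. After quantile normalization with an estimated correlation, camera called the mitosis and sterol synthesis lists (adjusted p = 0.00141 each) and the stress list (5.34e-04). The replication, hypoxia and astrocyte lists did not pass there. The p53 list had 0 of 22 past the threshold and a median of −0.062 (adjusted p = 0.81). In total 1 gene was higher and 4 lower (224 had an unadjusted p under 0.05), against 37 and 25 after quantile normalization and 14 and 6 after median scaling. With no filter the total was 0. It was 2, both lower, with the filter at the 60th percentile and with a replicate block. Of these 5 genes 0 passed in all planned settings that gave them a value. The actin ratio given above was lowest in the 36 h cultures without Cre. With those left out of the contrast, as chosen after seeing that ratio, 13 genes passed, 10 higher and 3 lower. This count at 60 h was 565 (347 higher, 218 lower) after quantile normalization and 183 (129 higher, 54 lower) after median scaling. At 36 h alone 3 genes passed as deposited and 0 in either of those settings. A response to 4OHT without Cre at 60 h was thus not excluded by the small pooled count.

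Whether the 4OHT response differed between CreER and no-Cre cultures was tested directly as an interaction over both times. The difference was largest for Cryab (1.81), Pygm (1.73), Cox8b (1.65), Igfbp5 (1.64), Gsn (1.57), Ptp4a3 (1.54), Anxa1 (1.42), Dcxr (1.39) and S100b (1.37), all with a higher response in CreER cultures. It was most negative for Car3 (−1.10), a carbonic anhydrase, and for Crb3 (−0.97), Spata5 (−0.97), Serinc4 (−0.91), Blm (−0.90), Lrr1 (−0.90), Brca1 (−0.88) and Dtl (−0.85). Other probe sets gave −0.11 and −0.33 for Spata5, −0.28 for Lrr1 and 0.63 for Igfbp5. Adjusted p lay between 7.10e-17 for Cryab and 0.0229 for Serinc4, from 4 CreER and 4 no-Cre arrays per treatment. The sign was the same at 36 h and 60 h for each of these genes, which the naming rule required. Of the replication genes 14 of 31 had a lower response in CreER cultures (24 when adjusted over the list alone), with a median difference of −0.52 (adjusted p = 7.54e-25; adjusted p = 0.31 with an estimated correlation), including Pola1 (−0.77) and Tk1 (−0.69). Of the mitosis genes 2 of 33, Ttk (−0.80) and Cenpf (−0.64), passed (23 when adjusted over the list alone), with a median of −0.42 (adjusted p = 9.15e-18; adjusted p = 0.37 with an estimated correlation). Of the p53 targets and CDK inhibitors 8 of 22 had a higher response (14 when adjusted over the list alone), with a median of 0.48 (adjusted p = 2.27e-18; adjusted p = 0.31 with an estimated correlation). Gadd45b (1.24), Trp53inp1 (1.06), Gadd45g (1.01) and Cdkn1a (0.93) led it. After quantile normalization with an estimated correlation, camera gave adjusted p = 4.7e-04 for replication, 1.6e-04 for mitosis and 3.6e-04 for p53. Of 20 immediate early genes 3 passed, Klf2 (1.27), Klf4 (0.90) and Dusp1 (0.64), with 5 when adjusted over the list alone and a median of 0.25 (adjusted p = 1.49e-06; adjusted p = 0.56 with an estimated correlation). Of 10 reported TLX-regulated genes 2 passed, S100b and Cdkn1a, also when adjusted over the list alone, with a median of 0.076 (adjusted p = 8.89e-04; adjusted p = 0.67 with an estimated correlation). By time the response was higher in CreER cultures for 69 genes and lower for 2 at 36 h, and for 38 and 36 at 60 h. After quantile normalization these numbers were 509 and 597 at 36 h and 432 and 443 at 60 h. In total, over both times, the response was higher in CreER cultures for 116 genes and lower for 62. This compares with 693 and 776 after quantile normalization and 425 and 771 after median scaling. The split was 111 and 142 with the actin ratio as a covariate, 82 and 117 without CreER vehicle 60 h replicate 2, 75 and 94 without CreER 4OHT 60 h replicate 2 and 77 and 82 without no-Cre 4OHT 60 h replicate 2. The total of 178 was 41 with no filter and 74 (38 higher, 36 lower) without the 36 h cultures lacking Cre, whose actin ratio was lowest. Without single arrays of CreER 4OHT 36 h it was 112 or 90 (replicate 1 or 2), of no-Cre vehicle 36 h 100 or 102, and of no-Cre 4OHT 36 h 114 or 113.

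In parallel cultures that received vehicle and no 4OHT, CreER and no-Cre cells differed in many genes. The vehicle arrays of CreER cultures had higher Thy1, a surface glycoprotein, at 2271 ± 364 against 157 ± 13.2 (SD, n = 4 each), and higher AI506816 (4.22), Esr1 (3.24), Clec14a (2.67), Gdpd3 (2.66), the glucose transporter Slc2a3 (2.41), the taurine transporter Slc6a6 (2.33) and Apln (2.27). They had lower Serpinh1, the collagen chaperone, at 151 ± 13.7 against 4458 ± 331 (SD, n = 4 each), and lower Ddit4l (−4.32), Tmlhe (−4.15), Sil1 (−3.80), the cerebellar transcription factor Zic1 (−3.69), Cd200 (−3.65), Ccl9 (−3.65) and Lama4 (−3.30). At each time both CreER arrays lay on the stated side of both no-Cre arrays. Adjusted p in limma ran from 5.28e-274 for Serpinh1 to 1.41e-56 for Clec14a. Such small values rest on the variance taken from the shared trend alone. After quantile normalization the smallest adjusted p of any gene in this comparison was 3.30e-16. Paip1 was called higher (3.46) by the probe set used, while its other probe set gave −1.27, so its direction is uncertain. The median of all genes shifted by −0.13, and list medians are given relative to it. Of 19 hypoxia and glycolysis genes 10 were higher and 0 lower (12 when adjusted over the list alone), with a relative median of 0.74 (adjusted p = 5.60e-14; adjusted p = 0.89 with an estimated correlation). Egln3 (2.42), Bnip3 (1.95), Pdk1 (1.57) and Adm (1.31) led it. Of 26 integrated and ER stress genes 11 were higher and 4 lower (13 and 4 when adjusted over the list alone), with a relative median of 0.38 (adjusted p = 0.00498; adjusted p = 0.93 with an estimated correlation), among them Cebpb (0.92), Trib3 (0.78) and, on the lower side, Xbp1 (−0.63). The other lists did not pass as sets, but 14 of 22 p53 targets and CDK inhibitors were lower and 3 higher (15 and 3 when adjusted over the list alone; adjusted p = 0.13), including Gadd45g (−1.93), Trp53inp1 (−1.14) and Cdkn2b (1.43). Clu (2.04) and Cd44 (1.19) were higher and Gja1 (−2.04) and S100b (−1.48) lower in the astrocyte list, in which 6 of 17 were higher and 5 lower (7 and 6 when adjusted over the list alone; adjusted p = 0.13). In total 607 genes were higher and 2024 lower in CreER cultures, 2631 of 7619, against 2225 and 1980 after quantile normalization and 2188 and 1781 after median scaling. The total was 1283 with the actin ratio as a covariate (643 higher, 640 lower) and 1328 (485 higher, 843 lower) without the no-Cre cultures of 36 h, whose actin ratio was lowest.

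**Figure D3:**
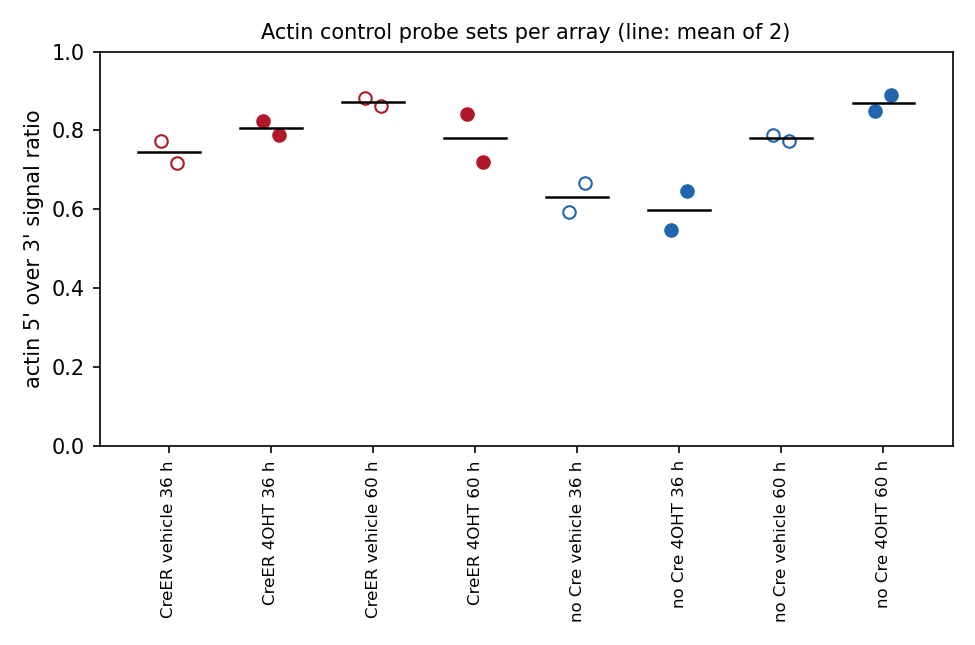
Ratio of the 5' to the 3' actin control probe set signal on each array (y axis, linear) in the 8 groups, with filled points for 4OHT, open points for vehicle and a line at the mean of 2 arrays. The 4 arrays without Cre at 36 h average 0.614 and those at 60 h average 0.825.

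Averaged over the 4 conditions, mitosis genes were lower at 60 h than at 36 h, with the larger values in CreER cultures. Relative to all genes the mitosis median was −0.54 in CreER vehicle, −0.60 in CreER 4OHT, −0.072 in no-Cre vehicle and −0.27 in no-Cre 4OHT cultures, and the replication median was −0.21, −0.51, −0.0083 and −0.20 in that order; these differences were not tested. Of 33 mitosis and G2/M genes 31 were lower at 60 h than at 36 h and 0 higher (32 lower when adjusted over the list alone), with a median of −0.44 (adjusted p = 6.48e-31; adjusted p = 0.35 with an estimated correlation). Among them were Top2a, from 2764 ± 836 to 1912 ± 723 (SD, n = 8 each), Nusap1 (−0.62), Aurkb (−0.59), Tpx2 (−0.58) and Bub1 (−0.57). Of 31 replication genes 23 fell (27 when adjusted over the list alone), with a median of −0.32 (adjusted p = 2.02e-14; adjusted p = 0.83 with an estimated correlation), including Rfc4 (−0.56) and Pola1 (−0.49). Insm1 (−0.74), a neurogenic transcription factor, and the kinesins Kif22 (−0.67) and Kif18a (−0.66) fell furthest. Kcnd3 (1.04), a potassium channel, rose from 73.0 ± 48.6 to 153 ± 51.9 (SD, n = 8 each). Nsd1 (1.04), Abcb8 (0.97), Smad5 (0.94), Spry4 (0.88) and the insulin receptor substrate Irs2 (0.88) rose too. Adjusted p lay between 7.62e-20 for Abcb8 and 1.88e-05 for Pola1. Both 60 h arrays lay below both 36 h arrays in each of the 4 conditions for Top2a, Nusap1, Tpx2, Bub1, Rfc4 and Insm1, and in fewer conditions for the other falling genes. Of the 12 genes with the largest rises, Rasal2 (0.76) was higher without overlap in each condition. Kcnd3, Abcb8, Smad5 and Spry4 were higher without overlap in the other 3 conditions, but in CreER cultures given 4OHT both of their 60 h arrays lay below both 36 h arrays. Nsd1 was higher without overlap only in cultures without Cre and also lower in CreER cultures given 4OHT. In that condition the actin ratio did not rise with time, and only there could 4OHT activate the recombinase. Of 20 immediate early genes 6 rose, also when adjusted over the list alone, including Klf2 (0.56). The median was −1.2e-04, or 0.076 relative to all genes, and the test pointed up (adjusted p = 4.97e-04; adjusted p = 0.96 with an estimated correlation). Of 19 hypoxia genes 3 rose, Bnip3 (0.39), Ndrg1 (0.34) and Egln3 (0.36), also when adjusted over the list alone, with a median of 0.027 (adjusted p = 7.72e-04; adjusted p = 0.96 with an estimated correlation). Other probe sets gave 0.19 for Abcb8, 0.56 for Smad5 and −0.18 for Nusap1. With the actin ratio as a covariate the mitosis median went from −0.44 to −0.22 and the replication median from −0.32 to −0.073. The mean actin ratio was 0.695 at 36 h and 0.826 at 60 h over the same arrays. In total 275 genes were higher and 622 lower at 60 h, 897 of 7619, against 1199 and 1396 after quantile normalization and 555 and 2920 after median scaling. The total was 31 with the actin ratio as a covariate (27 higher, 4 lower) and 402 (129 higher, 273 lower) in CreER cultures alone, both chosen after seeing the data. It was 452 with no filter and between 497 (without no-Cre 4OHT 36 h replicate 1) and 1482 (without CreER vehicle 60 h replicate 1) without single arrays.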

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

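For the fall of replication and mitosis genes and the rise of p53 targets after 4OHT in CreER cultures, quantile normalization and the difference of responses were planned, but their use as tests with set bounds and the actin covariate were chosen after the result was seen. Differences in array scaling were argued against, since the replication median stayed at −0.54 after quantile normalization. An effect of 4OHT without Cre as the whole cause was argued against by the difference of responses over both times, with a replication median of −0.52 (mitosis −0.42, p53 0.48, immediate early 0.25, reported TLX-regulated 0.076). A smaller part was not excluded, since that difference shows only a larger response in CreER cultures. Without Cre the mitosis median was −0.15 over both times, which averages 36 h and 60 h. From 36 h to 60 h without Cre, the median change of mitosis genes relative to all genes was −0.27 with 4OHT and −0.072 with vehicle. For replication genes it was −0.205 and −0.0083 in that order, and these differences were not tested. At 60 h without Cre, Mki67 and Chek1 were lower and Klf2 and Cdkn1a higher with 4OHT, without overlap, while Cryab and S100b overlapped. With the actin ratio as a covariate the replication median over both times was −0.66. That value decides little, because the ratio hardly differed over both times (0.794 with 4OHT, 0.808 with vehicle). By time the covariate moved the median from −0.44 to −0.34 at 36 h and from −0.82 to −0.98 at 60 h. RNA quality as the whole cause was argued against by the fall that remained at each time. Activity of the recombinase itself, which can damage DNA, and loss of Tlx cannot be told apart, because 0 arrays had active recombinase and no Tlx(f/Z) genotype; the pattern may therefore come from either.

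For the genes that differed between CreER and no-Cre cultures under vehicle, the test of probe sequence variants and the bound used for array scaling were chosen after the result was seen; quantile normalization itself was planned. Recombination without 4OHT as the main source of the difference was argued against for the 533 genes called at 60 h after 4OHT. Their genotype difference on the 36 h vehicle arrays, less the median of all genes and signed by the 4OHT change, had a median of −0.28. Of 10000 random gene sets, 95% gave −0.10 to −0.040. A smaller part was not excluded, because other differences between the cultures could outweigh it. The 36 h vehicle arrays also differed in actin ratio (0.745 in CreER, 0.630 without Cre), whose part in the median of −0.28 was not tested. Sequence variants under the probes were argued against for genes with a second probe set, whose change was 0.959 of that of the probe set used (median of 22 among 69 genes that differed 4-fold, 21 with the same sign). Array scaling as the source of the single calls was argued against, since 91.5% of the genes passed in the same direction after quantile normalization. In that setting 55.2% of all genes passed in either direction. For the excess of lower genes scaling was not argued against: 607 higher and 2024 lower became 2225 and 1980. A difference in the animals or cultures of origin was not tested and stays open.

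For the change between 36 h and 60 h, the tests of RNA quality and the bound used for array scaling were chosen after the result was seen; quantile normalization itself was planned. For the genes higher at 60 h, RNA quality was left undecided by their median of 0.25 in CreER cultures given 4OHT, where the actin ratio did not rise. A second test, added after the first, used 260 genes called in the other 3 conditions. Their median was 0.064 (bootstrap SE 0.020) in CreER cultures given 4OHT against 0.55 in those 3. The rise of these genes may thus follow RNA quality. Those cultures were also the only ones in which 4OHT could activate the recombinase. The test therefore cannot separate RNA quality from an effect of that treatment. For the mitosis genes RNA quality as the whole cause was argued against, for CreER cultures given 4OHT only, by a median of −0.60 there. With the actin ratio as a covariate their median was −0.22, which left a part of RNA quality undecided; that ratio rose with time in the other conditions. Array scaling was argued against by a median of −0.37 after quantile normalization.

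The counts over other splits of the same arrays were planned before the result was seen. The real count was reached by 1 of 35 splits (the real one) for 4OHT in CreER cultures (942 genes; highest other 159, a split by time) and by 1 of 35 for genotype (2631; highest other 16), and by 3 of 100 for time (897; highest other 2070). It was reached by 13 of 35 for 4OHT without Cre (5 genes; highest other 327, a split by time), by 5 of 100 for the difference of responses (178; highest other 1332) and by 10 of 35 for the difference between times (15; highest other 2841, a split of dimmer from brighter CreER arrays with median signals of 99.5 and 114.6). For these last counts chance was not excluded. The highest other counts, several times the real ones, point to a structure of the arrays beyond chance: for the 15 genes the splits above the real one included vehicle against 4OHT (981 genes) and 36 h against 60 h (409). The test therefore does not tell whether chance gave these counts.

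Probe sets without a single listed symbol were left out of the gene tests. Tested separately, 101 of 1007 passed the threshold after 4OHT in CreER cultures (22 higher, 79 lower) and 1 without Cre; these were not followed further here.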

How the results depend on the processing

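The numbers higher and lower with single arrays left out stand in the report where their order turned. For the difference between times, 7 higher and 8 lower, it turned without CreER vehicle 36 h replicate 1 (6 and 4), CreER vehicle 60 h replicate 1 (13 and 4), CreER 4OHT 36 h replicates 1 (4 and 3) and 2 (5 and 4), and CreER 4OHT 60 h replicate 1 (18 and 11). The actin covariate, the contrasts without no-Cre 36 h arrays and the estimated correlation after quantile normalization were chosen after the data were seen; the other settings were planned. Except where stated, the cause of a change was not tested.

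For 4OHT in CreER cultures over both times the count of 942 was 2951 after quantile normalization, 2513 after median scaling, 547 with no filter, 1458 with all probe sets and 580 with the CreER arrays alone. Without single arrays it ran from 520 to 1256; it was 622 without CreER vehicle 36 h replicate 2 and 520 and 584 without CreER 4OHT 36 h replicates 1 and 2. At 36 h the count of 199 was 1634, 1464, 14, 352 and 348 in those settings, in that order, and ran from 31 to 279 without single arrays. It was 58 and 78 without vehicle replicates 1 and 2 and 31 and 38 without 4OHT replicates 1 and 2. At 60 h the count of 533 was 2262, 1792, 253, 886 and 53 in those settings and 970 with the actin covariate. It ran from 321 (without CreER vehicle 60 h replicate 1) to 701.

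Without Cre the count of 5 was 62 after quantile normalization, 20 after median scaling, 8 with pseudocount 1, 0 with no filter, 2 with the filter at the 60th percentile, 2 with a replicate block, 29 with all probe sets, 9 with the no-Cre arrays alone and 13 at 60 h alone. It was 8 without either replicate of CreER vehicle 60 h or CreER 4OHT 60 h. It was 2 without CreER vehicle 36 h replicate 2, either CreER 4OHT 36 h replicate, no-Cre vehicle 60 h replicate 1 or no-Cre 4OHT 36 h replicate 1, and 1 without no-Cre vehicle 36 h replicate 2. The difference of responses, 178, was 1469 after quantile normalization, 1196 after median scaling, 41 with no filter and 74 at 60 h alone. It ran from 90 to 227 without single arrays: 112 and 90 without CreER 4OHT 36 h replicates 1 and 2, 100 and 102 without no-Cre vehicle 36 h replicates 1 and 2, and 114 and 113 without no-Cre 4OHT 36 h replicates 1 and 2.

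The difference of the CreER response between times, 15, was 167 after quantile normalization, 160 after median scaling, 0 with no filter, 7 with the filter at the 60th percentile, 26 with no trend, 110 with all probe sets, 8 with the CreER arrays alone and 9 with the actin covariate. It ran from 6 to 29 without single arrays: 7 and 9 without CreER 4OHT 36 h replicates 1 and 2, 29 and 6 without CreER 4OHT 60 h replicates 1 and 2. For genotype the count of 2631 was 4205 after quantile normalization, 3969 after median scaling, 4724 with all probe sets, 1283 with the actin covariate and 1328 at 60 h alone; it ran from 1911 to 3066 without single arrays. For time the count of 897 was 2595 after quantile normalization, 3475 after median scaling, 452 with no filter, 1988 with all probe sets, 31 with the actin covariate and 402 in CreER cultures alone. It ran from 497 to 1482: 572 without CreER vehicle 36 h replicate 2, 1482 without CreER vehicle 60 h replicate 1, 528 without CreER 4OHT 36 h replicate 2, 1467 without CreER 4OHT 60 h replicate 2, 569 without no-Cre vehicle 36 h replicate 1, 528 without no-Cre vehicle 60 h replicate 1, 497 without no-Cre 4OHT 36 h replicate 1 and 595 without no-Cre 4OHT 60 h replicate 2. All probe sets and no filter changed the number of tests by construction. A group left with 1 array is assumed by limma to vary like the others.

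Paip1 went from 3.46 to −1.55 between genotypes with pseudocount 1, which selected its other probe set. With the actin covariate Uroc1 turned to −0.40 in the difference between times and Nsd1 to −0.019 with time. Replicate numbers did not pair the groups: over 28 pairs of groups the correlation of replicate differences lay between −0.12 and 0.31, with 6 over 0.1; a replicate block gave 783 genes for 4OHT in CreER cultures. Of the named genes past the threshold, those that passed in the same direction in the planned settings that gave them a value were 24 of 24 for 4OHT in CreER cultures over both times and for time, 23 of 24 for genotype, 6 of 24 at 36 h, 22 of 24 at 60 h, 16 of 24 for the difference of responses, 0 of 5 without Cre and 0 of 15 between times. The filter at the 60th percentile gave no value for 6, 9, 16, 13, 8, 8, 3 and 8 of them in that order. Of the lists called with the preset correlation, those that also passed after quantile normalization with an estimated correlation were 4 of 7 for 4OHT in CreER cultures, 3 of 6 without Cre, 4 of 5 for the difference of responses, 0 of 2 for genotype and 2 of 4 for time. Settings for Nr2e1 gave no value.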

Other observations

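Levels of the same probe set can be set side by side between genotypes, while levels of different probe sets cannot. Mean signals in CreER and no-Cre cultures were 1736 and 1689 for the stem cell factor Sox2, 5650.3 and 5806 for the radial glial lipid-binding gene Fabp7, and 3437 and 3543 for the oligodendrocyte lineage factor Olig2. They lay further apart for the gap junction gene Gja1 (34.5 and 162) and for Clu (895 and 167). Stem and progenitor genes also differed, such as Nes (1776 and 2912), Sox9 (320 and 691), Pax6 (182 and 328) and Hmga2 (582 and 236). Under vehicle 4 of 23 measured genes of that list were higher and 9 lower in CreER cultures. Of genes with a probe set, 23 of 29 stem and progenitor, 17 of 26 astrocyte, 12 of 29 neuron, 7 of 19 oligodendrocyte lineage and 1 of 16 microglial genes passed the filter. Sox1, Hes5, Gli1, Gli2 and Fut4 were among the progenitor genes below it, so these numbers were not read as a cell type. The Y-linked gene Eif2s3y had a mean signal of 223 in CreER and 254 in no-Cre arrays. Kdm5d had 207 and 199, and Uty lay further apart at 124 and 191. Under vehicle 1 of 3 measured sex-linked genes passed the threshold, lower in CreER cultures.

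Genes that changed at 60 h after 4OHT in CreER cultures more often moved in the direction of the level of cultures without Cre than away from it. Here the genotype difference was taken less the median of all genes, while the 4OHT change was not shifted. On 36 h vehicle arrays, which share nothing with the 60 h call, 20.5% of these 533 genes had such a difference with the sign of their 4OHT change, against 39.9% of all genes. Shares without that shift are not given here. The actin ratio on those arrays was 0.745 in CreER and 0.630 in no-Cre cultures, and its part in these shares was not tested. Cryab averaged 56.4 in CreER vehicle arrays and 223 after 4OHT, with 599 in no-Cre vehicle arrays; S100b averaged 203, 453 and 591 in the same order. Cdkn1a averaged 1540, 3015 and 2285 by the probe set used, past that level, and 531, 1598 and 2466 by another, short of it. Mki67 went the other way, with 1969, 1124 and 2714. Whether this reflects culture state was not tested.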
